A study of Homo sapiens with 6 samples.

How the data were processed

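RNA-seq libraries from 6 samples of cells labelled Huh7 were used, 3 from control cells with the genotype label WT and 3 from cells with SRSF10 knocked down. Per the labels' protocols, total RNA was extracted with TRIzol, RNA above a minimum integrity number was cleaned up and treated with DNase, libraries were made with a Vazyme VAHTS V6 kit, and an Illumina NovaSeq instrument was used. Per the submitters' processing notes, FastQC 0.11.9 and Trim Galore 0.6.5-1 were run and the genome build was GRCh38. The aligner, the counting program, the annotation release, the strand setting and the depth of each library are not given in the sources used here.

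The authors deposited FPKM values, which are fragments divided by gene length and by the mapped fragments of the library. They are in a table of the whole series and in a file per sample, and the 60623 values of each sample were identical in both. Zeros are included. Because FPKM are already divided by depth and length, a count model was not run. The test planned before the data were examined was a count test, with limma on log2 FPKM in its place if there were no counts, and the latter is the main test here. Fold changes are differences of log2(FPKM + 1), which understates the change of genes with low values. FPKM are shares of a total, so a rise in some abundant transcripts lowers the values of all others. Mitochondrially encoded genes made up 27.5% to 29.7% of the summed FPKM.

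Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 12191. With 3 libraries per group a gene can pass through 1 group alone, and its direction is then largely set by the filter. Named genes under 1 FPKM in every control include CDH6, CD24, HLA-B, TRAF1, F2 and APOE. SOST was under 1 FPKM in every knockdown library. The model was limma 3.58.1 in R 4.3.3, with a trend on mean expression, the group as the only term and Benjamini-Hochberg adjustment over all tested genes. The threshold was an adjusted p of 0.05. Levels are means ± SD over the 3 libraries of a group. For SRSF10 an exact two-sided permutation test was run beside the model. Gene lists, 42 in all, were written before the data were examined, and all of their 1020 symbols were found in the files. The 39 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. With the correlation estimated for each list instead, no list passed, and the smallest adjusted p was 0.136. Some genes are in more than 1 list.

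The rule for the genes named was also fixed before the data were examined. It takes a set of preset genes and the 10 protein-coding genes in each direction with the largest fold change. The latter had to pass the threshold, with a mean of at least 1 FPKM in a group and no overlap between the groups. It also takes the 5 genes in each direction with the smallest adjusted p and, in each list described, up to 4 members with the smallest adjusted p and any member needed to show the other direction. Cell type markers come from lists fixed at the same time. Some genes that the rule takes are not reported here. Any gene named outside this rule is said to have been chosen after its values were seen.

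Positions, exon lengths and overlaps come from GENCODE release 29 on GRCh38, in which 12146 of the 12191 tested genes were found by identifier. The release used by the authors can differ. Exons of 51 of the 128 genes the rule takes overlap exons of another gene there, and without a known strand setting the reads of such pairs cannot be told apart. Chromosome arms were separated at approximate centromere positions.

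Depth was estimated from low FPKM values, which, multiplied by exon length and a trial depth, should give whole numbers of fragments. The smallest depth that did so put 86.1% to 86.9% of values of up to 6.5 fragments within 0.05 of a whole number, where chance gives 10%. These depths were used only to describe precision. The steps were tested on simulated data with those depths and the replicate spread of these libraries, with 200 genes changed between knockdown and control. Among 12057 simulated genes tested, those changed by 1 on the log2 scale were recovered in 98% (lower) and 96% (higher) of cases, those changed by 0.5 in 80% and 78%, with 14 false calls. These were 7.4% of all calls, above the 0.05 aimed at. Far fewer genes were changed in the simulation than were called in the real libraries. Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9 were used for depth and plots.

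Alternatives listed before the data were examined were no filter on low values, a pseudocount of 0.1, the replicate number as a block, leaving out each library in turn, and the estimated correlation in camera. Those chosen after seeing the data were median-of-ratios scaling, quantile normalization, rescaling without mitochondrially encoded genes, a filter of 5 FPKM, limma without the trend, removal of a trend on gene length and GC content, and leaving out the genes of chromosome 3. Splicing was not analysed here, since the values are per gene.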

Results

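The transcriptome was measured by RNA-seq in cells labelled Huh7, a human hepatocellular carcinoma line. There were 3 control libraries and 3 libraries with SRSF10 knocked down, by a short hairpin RNA according to the series title. The controls have the genotype label WT and titles that start with NC. Those labels do not say whether the controls carried a control hairpin. If they did not, effects of the hairpin or its delivery cannot be told apart from those of lower SRSF10. The comparison asks how gene expression differs when SRSF10, a splicing factor of the SR protein family, is lowered. The files give FPKM values for 60623 genes. The depth estimated from the steps between low values was 12720000 to 14350000 fragments assigned to genes per library. Among genes with at least 500 estimated fragments, the median coefficient of variation between replicates was 4.51% in the controls and 3.48% in the knockdown. Counting error alone would give 2.97% and 2.99%. Log2 values correlated across tested genes with r = 0.986 to 0.988 within a group and 0.971 to 0.976 between groups, and genes are not independent replicates. No label says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

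SRSF10 itself was lower in every knockdown library. SRSF10 (ENSG00000188529, GRCh38 chromosome 1, 23964804 to 23980927, minus strand) was at 18.6, 19.5 and 19.8 FPKM in the controls and at 10.6, 10.8 and 10.6 FPKM in the knockdown. The mean was 44.8% lower in the knockdown, at 19.3 ± 0.61 and 10.7 ± 0.12 FPKM in control and knockdown (SD, n = 3 per group; exact two-sided permutation p = 0.1, the smallest possible). The log2 fold change was -0.80 with an SE of 0.038, and the limma adjusted p was 0.000166. No exon of another gene overlaps those of SRSF10 in the annotation used.

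Knockdown libraries differed from controls across a large part of the transcriptome, mostly by small amounts. Of 12191 tested genes, 1542 were higher and 1525 lower in the knockdown (limma, adjusted p under 0.05), and the median size of their log2 change was 0.31. Among them 97 rose and 34 fell by 2-fold or more on the log2(FPKM + 1) scale. Of the higher genes 1427 were protein-coding, and of the lower genes 1398. For 42.7% of tested genes the 3 values of a group all lay above those of the other, where chance gives 10%. Without knockdown replicate 1, 2 or 3, the higher genes numbered 952, 943 and 894 and the lower genes 1015, 982 and 964, and without replicate 1 or 3 those 2-fold higher numbered 60 and 58. The filter still asked for 3 libraries in those fits, so genes that reach 1 FPKM in the knockdown alone were not tested. This covers a small part of the drop. Of the 3067 called genes 2943 were still tested without knockdown replicate 1, 2 or 3, and 1889, 1839 and 1788 still passed. With a pseudocount of 0.1 the genes changed 2-fold numbered 196 higher and 79 lower, and with a 5 FPKM filter 39 and 15. With no filter 1013 genes were lower.

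On the log2(FPKM + 1) scale the largest rises were in GPNMB, a transmembrane glycoprotein of lysosomes and melanosomes, and TFEC, a transcription factor of the MITF and TFE family. Among the 10 largest rises on that scale, the order by the ratio of mean FPKM was CDH6 (9.35-fold), TFEC (9.28-fold), SPARC (8.97-fold), CD24 (8.54-fold) and GPNMB (8.43-fold), since the pseudocount shrinks the change of genes with low values, and some genes with control values near 0 had higher ratios. GPNMB (ENSG00000136235, chromosome 7, 23235967 to 23275108) went from 2.25 ± 0.28 to 18.98 ± 0.52 FPKM (SD, n = 3 per group). Its log2 fold change was 2.62 (SE 0.069, limma adjusted p = 3.45e-05). TFEC (ENSG00000105967, chromosome 7, 115935148 to 116159896) went from 1.05 ± 0.18 to 9.76 ± 0.12 FPKM, a log2 fold change of 2.39 (SE 0.073, limma adjusted p = 4.95e-05). SPARC, a matricellular protein, rose from 1.04 ± 0.28 to 9.31 ± 0.502 FPKM, and the cadherin CDH6 from 0.753 ± 0.27 to 7.04 ± 0.79 FPKM. The others of the 10 largest rises were in the adhesion molecule VCAM1, the sulfatase SULF2, the chemokine CXCL5, the surface protein CD24, the ubiquitin ligase subunit FBXO32 and the tight junction protein CLDN2. Their log2 fold changes ran from 1.72 to 2.01. BAAT, which conjugates bile acids, rose from 1.18 ± 0.064 to 5.62 ± 0.12 FPKM. ITIH2, an inter-alpha-trypsin inhibitor heavy chain, rose from 17.7 ± 0.85 to 43.1 ± 1.9 FPKM.

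The largest fall on that scale was in SOST, a secreted inhibitor of Wnt signalling, from 5.73 ± 2.7 to 0.246 ± 0.075 FPKM (log2 fold change -2.34, SE 0.31, limma adjusted p = 0.00305). EGR1, an immediate early transcription factor, fell from 37.02 ± 3.7 to 10.4 ± 1.5 FPKM. The cell surface glycoprotein CEACAM6 fell from 235 ± 19 to 86.8 ± 2.7 FPKM (log2 fold change -1.42, SE 0.062, limma adjusted p = 0.000159). The ligand WNT5A fell from 19.6 ± 3.95 to 5.54 ± 0.51 FPKM and the transcription factor GATA2 from 13.1 ± 2.8 to 4.02 ± 0.52 FPKM. Both lie on chromosome 3, whose genes were lower as a group, but by far less. The log2 fold changes were -1.64 for WNT5A and -1.48 for GATA2, against medians of -0.27 on the short arm and -0.13 on the long arm. LOC105373347, CPLX2, CRABP2, ABCA4 and PDZK1 were the others of the 10 largest falls, with log2 fold changes of -1.61 to -1.12. GOLM1, a Golgi membrane protein, fell from 60.7 ± 2.9 to 32.4 ± 1.1 FPKM, and the transcription factor BTF3 from 86.7 ± 2.6 to 53.3 ± 1.7 FPKM.

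**Figure D1:**
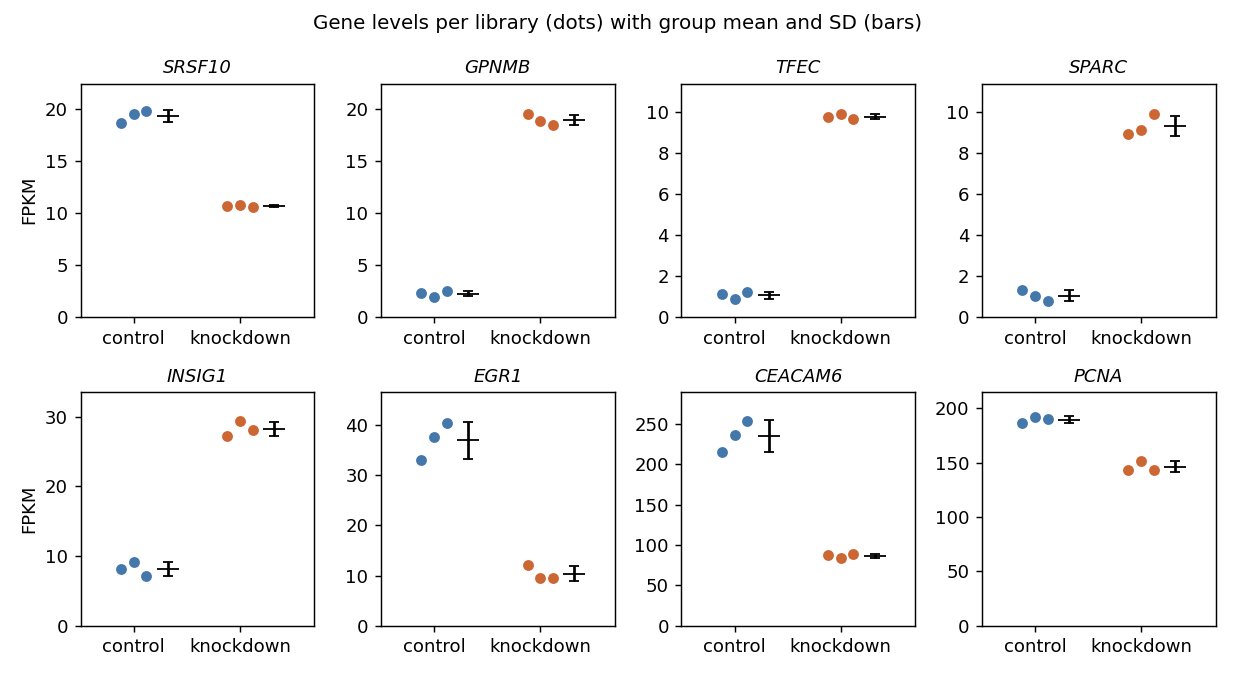
FPKM (vertical axis, from 0) of SRSF10, GPNMB, TFEC, SPARC, INSIG1, EGR1, CEACAM6 and PCNA in the 3 control and 3 knockdown libraries, 1 dot per library, with the group mean and SD. In every panel the 3 knockdown values lie apart from the 3 control values, as for SRSF10 at 10.6 to 10.8 against 18.6 to 19.8 FPKM.

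Genes of cholesterol synthesis rose together. In that list 19 of 24 tested members rose and 0 fell (21 rose and 0 fell adjusted over the list alone), with a median log2 fold change of 0.48 (camera adjusted p = 6.63e-13, adjusted p = 0.136 with an estimated correlation). INSIG1, a sterol-responsive regulator of the pathway, rose from 8.16 ± 1.04 to 28.3 ± 1.04 FPKM, and the epoxidase SQLE from 23.9 ± 1.5 to 42.2 ± 0.69 FPKM. The sterol carrier STARD4 rose from 2.86 ± 0.12 to 5.93 ± 0.45 FPKM. In fatty acid and triglyceride synthesis 9 of 18 tested members rose and 0 fell (9 rose and 1 fell adjusted over the list alone) (camera adjusted p = 0.00103, adjusted p = 0.136 with an estimated correlation). The desaturases FADS1 (19.3 ± 0.84 to 33.03 ± 1.1 FPKM) and FADS2 (14.6 ± 1.6 to 27.3 ± 0.94 FPKM) rose, and their exons overlap. So did the lipid droplet protein PNPLA3 (1.38 ± 0.19 to 4.59 ± 0.21 FPKM) and the acetyl-CoA synthetase ACSS2 (4.4001 ± 0.11 to 8.35 ± 0.58 FPKM). With the preset correlation camera called 2 to 14 lists in the other 9 splits of the 6 libraries, against 20 in the real split.

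Among cytokines and chemokines 12 of 20 tested members rose and 0 fell (17 rose and 0 fell adjusted over the list alone), with a median log2 fold change of 0.52 (camera adjusted p = 3.73e-08, adjusted p = 0.219 with an estimated correlation). TGFB1 rose from 23.4 ± 0.85 to 39.4 ± 0.99 FPKM, LIF from 4.63 ± 0.65 to 10.3 ± 0.29 FPKM, CXCL5 from 12.8 ± 2.8 to 45.9 ± 5.3 FPKM and IL1B from 1.799 ± 0.52 to 6.33 ± 0.37 FPKM. Exons of TGFB1 overlap those of HNRNPUL1. Among NF-kB targets and feedback genes 11 of 18 tested members rose and 0 fell (11 rose and 0 fell adjusted over the list alone) (camera adjusted p = 3.34e-05, adjusted p = 0.291 with an estimated correlation). The feedback inhibitor TNFAIP3 rose from 3.399 ± 0.36 to 7.32 ± 0.49 FPKM, BIRC3 from 4.82 ± 0.86 to 14.05 ± 1.6 FPKM, TRAF1 from 0.707 ± 0.066 to 1.95 ± 0.12 FPKM and the adhesion molecule ICAM1 from 32.2 ± 1.6 to 43.7 ± 2.4 FPKM.

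In antigen presentation 11 of 15 tested members rose and 0 fell (11 rose and 0 fell adjusted over the list alone) (camera adjusted p = 7.901e-08, adjusted p = 0.136 with an estimated correlation). HLA-C rose from 14.2 ± 0.45 to 25.7 ± 0.99 FPKM, HLA-E from 41.7 ± 0.92 to 53.4 ± 0.89 FPKM, the peptide transporter TAP1 from 2.94 ± 0.205 to 5.28 ± 0.29 FPKM and HLA-B from 0.677 ± 0.196 to 2.93 ± 0.43 FPKM. HLA genes are close copies of each other, so their reads can be split between them. Exons of HLA-B and HLA-C also overlap in the annotation used. Interferon-stimulated genes were not called: 4 of 15 tested members rose and 0 fell (4 rose and 1 fell adjusted over the list alone) (camera adjusted p = 0.0715, adjusted p = 0.307 with an estimated correlation). They were called higher without knockdown replicate 2 (adjusted p = 0.03204) and with no filter (0.01205), in a range of 0.01205 to 0.532.

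In autophagy and lysosome 14 of 26 tested members rose and 2 fell (15 rose and 2 fell adjusted over the list alone) (camera adjusted p = 3.41e-05, adjusted p = 0.136 with an estimated correlation). The phosphoinositide-binding protein WIPI1 rose from 2.13 ± 0.075 to 4.83 ± 0.297 FPKM, the sialidase NEU1 from 17.5 ± 0.71 to 25.8 ± 1.2 FPKM, the cholesterol exporter NPC1 from 33.2 ± 2.7 to 50.8 ± 0.97 FPKM and the autophagy kinase ULK1 from 5.29 ± 0.29 to 7.37 ± 0.21 FPKM. The glycosidases GLA (71.2 ± 4.4 to 56.4 ± 1.4 FPKM) and GAA (5.16 ± 0.11 to 4.196 ± 0.36 FPKM) fell. In the unfolded protein response 13 of 21 tested members rose and 1 fell (14 rose and 1 fell adjusted over the list alone) (camera adjusted p = 3.41e-05, adjusted p = 0.219 with an estimated correlation). The chaperones HSPA5 (158 ± 7.9 to 210.5 ± 4.6 FPKM), PDIA4 (98.5 ± 1.2 to 128 ± 3.6 FPKM) and CALR (211 ± 5.6 to 254 ± 3.3 FPKM) and the transcription factor XBP1 (20.2 ± 0.96 to 26.2 ± 1.1 FPKM) rose. EDEM1, on chromosome 3, fell from 16.2 ± 0.67 to 13.2 ± 0.71 FPKM. In the integrated stress response 9 of 25 tested members rose and 0 fell (13 rose and 0 fell adjusted over the list alone) (camera adjusted p = 2.38e-06, adjusted p = 0.207 with an estimated correlation). The log2 fold changes were 0.33 for PSPH, 0.33 for TRIB3, 0.51 for STC2 and 0.55 for NUPR1.

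Mesenchymal and extracellular matrix genes were higher as well: 11 of 20 tested members rose and 1 fell (12 rose and 1 fell adjusted over the list alone) (camera adjusted p = 0.000254, adjusted p = 0.136 with an estimated correlation). Beside SPARC, the collagenase MMP1 rose from 1.82 ± 0.22 to 5.64 ± 0.81 FPKM and the integrin ITGA5 from 10.1 ± 0.49 to 15.1 ± 0.63 FPKM. MMP2 fell from 8.63 ± 0.16 to 6.96 ± 0.47 FPKM. Among YAP/TAZ targets 7 of 15 tested members rose and 2 fell (9 rose and 2 fell adjusted over the list alone) (camera adjusted p = 0.0258, adjusted p = 0.291 with an estimated correlation). AXL rose from 8.23 ± 1.01 to 16.9 ± 1.8 FPKM and NT5E from 22.2 ± 3.9 to 44.2 ± 1.7 FPKM. CCN2, a target widely used to read this pathway, fell from 9.18 ± 0.61 to 6.21 ± 0.89 FPKM, and AMOTL2, on chromosome 3, from 10.6 ± 0.1995 to 8.74 ± 0.19 FPKM. The YAP/TAZ call was lost without control replicate 1 (adjusted p = 0.0557), with no filter (0.0609) and with a 5 FPKM filter (0.292), and its adjusted p ran from 0.00919 to 0.292 over the alternatives.

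Liver transcripts were scarce in all 6 libraries. AFP was at 0.818 FPKM in the controls and 0.882 FPKM in the knockdown, ALB at 0.1496 and 0.624 FPKM, and APOA1 at 0.0531 and 0.0522 FPKM. TTR and APOA2 were listed at 0 in every library. These 5 liver transcripts were chosen after their values were seen. Of 36 genes for secreted liver proteins 8 passed the filter, and 4 of 8 tested members rose and 0 fell (4 rose and 0 fell adjusted over the list alone) (camera adjusted p = 0.0156, adjusted p = 0.289 with an estimated correlation). Those that rose were ITIH2, AMBP (4.303 ± 0.52 to 7.38 ± 0.42 FPKM), the prothrombin gene F2 (0.954 ± 0.051 to 2.65 ± 0.56 FPKM) and APOE (0.3402 ± 0.11 to 1.76 ± 0.43 FPKM). F2 and APOE were under 1 FPKM in every control, so they passed the filter only through the knockdown libraries. Without 1 of those libraries they could not be tested. That call was lost without knockdown replicate 1 (adjusted p = 0.156), 2 (0.169) or 3 (0.0886) and with no filter (0.0582), in a range of 0.00974 to 0.169.

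Among fetal liver and carcinoma markers 5 of 10 tested members rose and 0 fell (5 rose and 0 fell adjusted over the list alone) (camera adjusted p = 0.00776, adjusted p = 0.219 with an estimated correlation). CD24 (0.461 ± 0.199 to 3.94 ± 0.67 FPKM), PEG10 (4.46 ± 0.71 to 8.96 ± 0.29 FPKM), SPP1 (252 ± 17 to 353 ± 14 FPKM) and SOX9 (1.32 ± 0.55 to 4.34 ± 0.81 FPKM) rose. With a 5 FPKM filter the adjusted p was 0.139, in a range of 0.00442 to 0.139. Among amino acid and urea cycle enzymes 5 of 8 tested members rose and 0 fell (6 rose and 0 fell adjusted over the list alone) (camera adjusted p = 0.00326, adjusted p = 0.317 with an estimated correlation). The tryptophan dioxygenase TDO2 (4.86 ± 0.65 to 11.8 ± 1.6 FPKM) and the glutamine synthetase GLUL (12.2 ± 0.42 to 14.6 ± 0.38 FPKM) rose.

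Among G1/S and DNA replication genes 0 of 36 tested members rose and 28 fell (0 rose and 29 fell adjusted over the list alone), with a median log2 fold change of -0.27 (camera adjusted p = 1.78e-11, adjusted p = 0.219 with an estimated correlation). The helicase subunit MCM2 fell from 50.9 ± 0.98 to 37.2 ± 0.78 FPKM, CDC45 from 18.7 ± 0.47 to 14.02 ± 0.22 FPKM, the polymerase clamp PCNA from 189.7 ± 2.95 to 146 ± 5.05 FPKM and the clamp loader subunit RFC4 from 24.1 ± 0.91 to 17.8 ± 0.35 FPKM. MCM2 and RFC4 lie on chromosome 3. Among replication-dependent histones 0 of 9 tested members rose and 4 fell (0 rose and 5 fell adjusted over the list alone) (camera adjusted p = 0.0236, adjusted p = 0.3596 with an estimated correlation). H1-2 fell from 41.7 ± 7.5 to 23.6 ± 2.7 FPKM and H2BC5 from 9.88 ± 0.81 to 6.43 ± 0.75 FPKM. This call was lost without knockdown replicate 3 (adjusted p = 0.0812) and with a 5 FPKM filter (0.0511), in a range of 0.00523 to 0.0812. G2/M and mitosis genes were not called: 3 of 33 tested members rose and 3 fell (3 rose and 3 fell adjusted over the list alone) (camera adjusted p = 0.316). AURKA rose from 41.1 ± 0.73 to 49.7 ± 0.47 FPKM and TOP2A fell from 105 ± 2.7 to 87.2 ± 1.3 FPKM.

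In ribosome biogenesis 1 of 30 tested members rose and 20 fell (1 rose and 22 fell adjusted over the list alone) (camera adjusted p = 3.73e-08, adjusted p = 0.136 with an estimated correlation). GNL3, on chromosome 3, fell from 60.03 ± 1.6 to 44.5 ± 0.66 FPKM, NOLC1 from 72.5 ± 1.8 to 58.1 ± 1.7 FPKM and the transcription factor MYC from 34.2 ± 1.4 to 25.4 ± 0.73 FPKM. The helicase gene DDX10 rose (7.45 ± 0.35 to 8.42 ± 0.084 FPKM). Among ribosomal protein genes 0 of 53 tested members rose and 7 fell (0 rose and 7 fell adjusted over the list alone) (camera adjusted p = 0.0459, adjusted p = 0.767 with an estimated correlation). Over all 12191 tested genes 1525 fell, a similar share. Of the 7 that fell 5 lie on chromosome 3, RPL14, RPL24 and RPL32 among them. Without the genes of chromosome 3 that list's adjusted p was 0.128. It ran from 0.0024005 to 0.629 over the alternatives, 10 of which ended the call, among them leaving out control replicate 1 (0.0555), control replicate 2 (0.291) or knockdown replicate 1 (0.629).

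Among SR proteins and their regulators, SRSF10 left out, 0 of 24 tested members rose and 10 fell (1 rose and 11 fell adjusted over the list alone) (camera adjusted p = 0.00136, adjusted p = 0.289 with an estimated correlation). SRSF2 fell from 53.3 ± 3.2 to 41.3 ± 0.62 FPKM, TRA2B, on chromosome 3, from 20.7 ± 0.4996 to 17.3 ± 0.042 FPKM, the SR protein kinase SRPK1 from 24.9 ± 1.1 to 20.3 ± 0.071 FPKM and LUC7L3 from 22.8 ± 0.84 to 19.4 ± 0.399 FPKM. Exons of SRSF2 overlap those of MFSD11. Among hnRNP genes 0 of 27 tested members rose and 6 fell (0 rose and 6 fell adjusted over the list alone) (camera adjusted p = 0.00103, adjusted p = 0.219 with an estimated correlation). HNRNPL fell from 35.3 ± 0.49 to 28.2 ± 0.98 FPKM and HNRNPDL from 37.8 ± 0.83 to 31.9 ± 1.2 FPKM. In the core spliceosome 1 of 33 tested members rose and 11 fell (1 rose and 11 fell adjusted over the list alone) (camera adjusted p = 0.000254, adjusted p = 0.219 with an estimated correlation). The log2 fold changes were -0.21 for SNRNP70, -0.22 for SF3A3 and -0.20 for SNRNP200, and 0.12 for SF3A1, which rose. The medians of the SR protein, hnRNP and spliceosome lists were -0.12, -0.11 and -0.10.

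**Figure D2:**
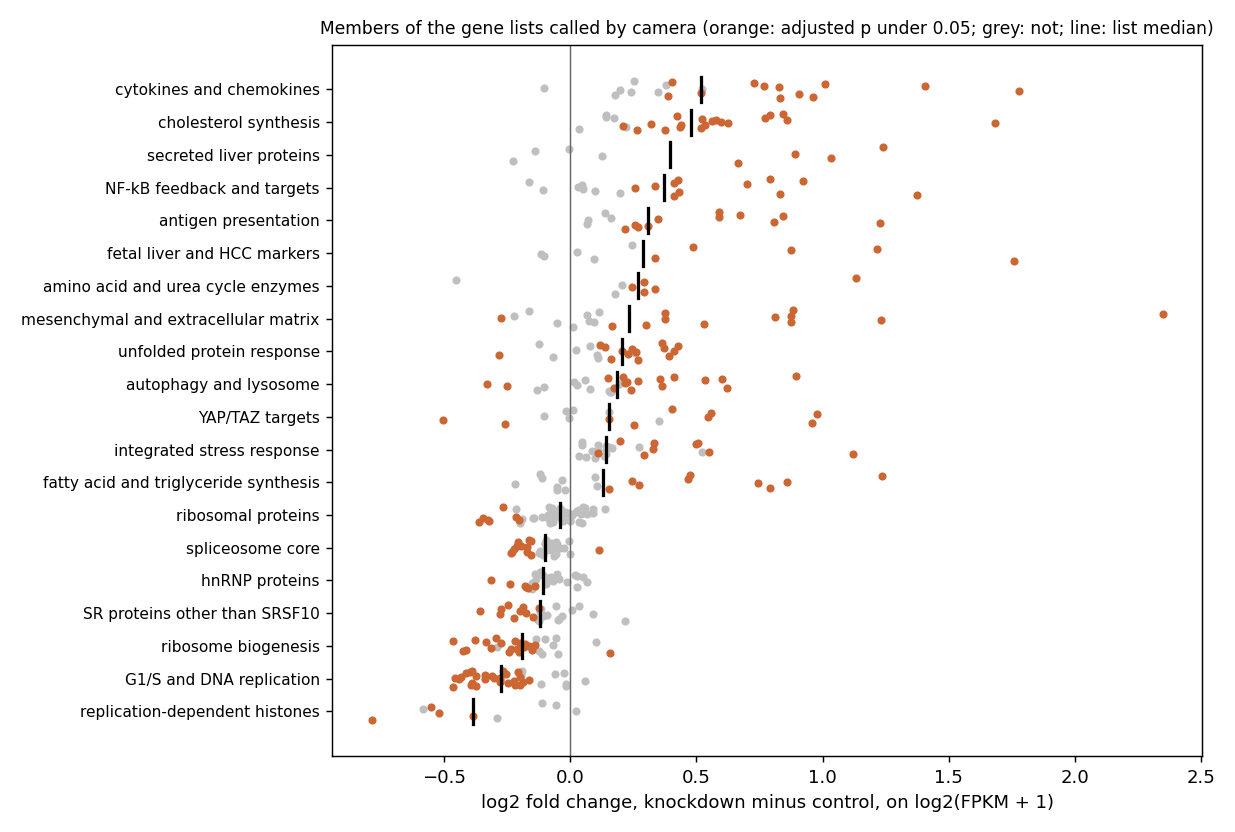
Log2 fold changes (horizontal axis, knockdown minus control on log2(FPKM + 1)) of the tested members of the 20 gene lists called by camera at the preset correlation, 1 dot per gene, orange where the limma adjusted p is under 0.05, with lines at the list medians. The medians run from -0.38 for replication-dependent histones to 0.52 for cytokines and chemokines, above 0 in the 13 lists called higher and below 0 in the 7 called lower.

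Glycolysis genes moved in both directions. In that list 5 of 22 tested members rose and 3 fell (5 rose and 3 fell adjusted over the list alone), and it was not called (camera adjusted p = 0.2999). The kinase PDK1 rose from 1.65 ± 0.12 to 2.99 ± 0.11 FPKM, the lactate transporter SLC16A3 from 5.07 ± 0.498 to 7.66 ± 0.43 FPKM and PFKP from 35.4 ± 1.4 to 43.2 ± 1.5 FPKM, whereas PFKFB3 fell from 22.4 ± 1.8 to 15.6 ± 0.69 FPKM. Of the preset glycolytic genes, the glucose transporter SLC2A1 was at 19.9 ± 1.2 and 22.7 ± 2.4 FPKM (limma adjusted p = 0.148) and HK1 at 34.4 ± 0.73 and 35.6 ± 1.5 FPKM (0.445). LDHA was at 129.9 ± 3.2 and 138 ± 11 FPKM (0.334) and PKM at 489 ± 14 and 467 ± 8.5 FPKM (0.227), so none of the 4 passed the threshold. The macrophage growth factor gene CSF1 was at 35 ± 3.1 and 39.6 ± 1.6 FPKM (0.102). MYB, HK2, CD274 and CCL2 were below the filter. MYB was at 0.585 ± 0.16 and 0.256 ± 0.082 FPKM, HK2 at 0.0738 ± 0.028 and 0.1604 ± 0.0402 FPKM and CD274 at 0.0612 ± 0.032 and 0.0861 ± 0.057 FPKM, and CCL2 was above 0 in 1 knockdown library only. Without a filter their limma adjusted p-values were 0.164, 0.227, 0.746 and 0.703.

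Among immediate early genes 1 of 22 tested members rose and 8 fell (3 rose and 8 fell adjusted over the list alone), and the list missed the threshold (camera adjusted p = 0.0561, adjusted p = 0.475 with an estimated correlation). Beside EGR1 and MYC, JUN fell from 41.1 ± 4.3 to 24.9 ± 2.1 FPKM and ZFP36 from 34.5 ± 1.2 to 24.4 ± 1.5 FPKM, and DUSP5 rose from 27.1 ± 1.99 to 38.6 ± 2.5 FPKM. The list was called lower without chromosome 3 (adjusted p = 0.02895), with no filter (0.00595) and without control replicate 1 (0.03896) or 2 (0.0111), in a range of 0.00595 to 0.2805. The remaining tested lists were not called. Camera adjusted p-values were 0.127 for nuclear oxidative phosphorylation genes, 0.156 for NRF2 targets, 0.213 for Wnt targets, 0.232 for heat shock proteins and 0.283 for hypoxia. Nuclear oxidative phosphorylation genes were called lower without control replicate 3 (adjusted p = 0.0179), without knockdown replicate 2 (0.0315) and with no filter (0.0173), in a range of 0.0173 to 0.641. NRF2 targets were called lower without control replicate 3 (0.0466) and with no filter (0.0279), in a range of 0.0279 to 0.454, and Wnt targets with no filter (0.0269), in a range of 0.0269 to 0.497. The adjusted p-values were 0.381 for fatty acid oxidation, 0.381 for p53 targets, 0.496 for mitochondrially encoded genes and 0.531 for the TCA cycle. For liver transcription factors, epithelial junctions, cytochrome P450 genes, bile acid genes and gluconeogenesis they were 0.719, 0.837, 0.9103, 0.9103 and 0.914. The bile acid list had a median below 0 but a mean and test above it, and the gluconeogenesis list a median and mean above 0 but a test below it.

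Markers of other cell types were mostly under the filter. Of 20 macrophage and leukocyte markers ITGAM alone was tested (1.09 ± 0.18 to 1.73 ± 0.25 FPKM, limma adjusted p = 0.0415), and of 14 fibroblast and stellate markers LUM alone (4.403 ± 0.61 to 9.502 ± 0.67 FPKM, adjusted p = 0.000928). Of 12 endothelial markers 3 were tested and all 3 rose, ESAM from 6.37 ± 0.68 to 11.5 ± 0.35 FPKM, KDR from 0.502 ± 0.27 to 3.09 ± 0.43 FPKM and PECAM1 from 5.28 ± 0.62 to 6.85 ± 0.57 FPKM. KDR, with a low control mean, passed the filter through the knockdown libraries. Among cholangiocyte markers 3 of 7 tested members rose and 2 fell (4 rose and 3 fell adjusted over the list alone), and the list was not called (camera adjusted p = 0.459). SOX9 and SPP1 were among those that rose, and KRT7 fell from 3.16 ± 0.66 to 1.14 ± 0.23 FPKM.

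Genes of chromosome 3 were lower as a group in the knockdown. On its short arm 290 of 326 tested genes had a log2 fold change below 0, and the median was -0.27. There 185 genes fell and 4 rose (limma, adjusted p under 0.05). On the long arm 130 of 392 fell and 30 rose, with a median of -0.13. Of the 39 other arms with 50 or more tested genes, none had a median beyond 0.0561 in size. Among short-arm genes with a mean of at least 5 FPKM, the median difference from the control mean was -0.31, -0.29 and -0.27 in the knockdown libraries. In the controls it was 0.0046, 0.0067 and -0.014. Chromosome 3 held 5.89% of the tested genes and 20.7% of those called lower. With its 718 tested genes left out, 1469 genes were higher and 1177 lower. Of the 20 called lists the ribosomal proteins alone then lost their call, and the immediate early genes gained one.

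**Figure D3:**
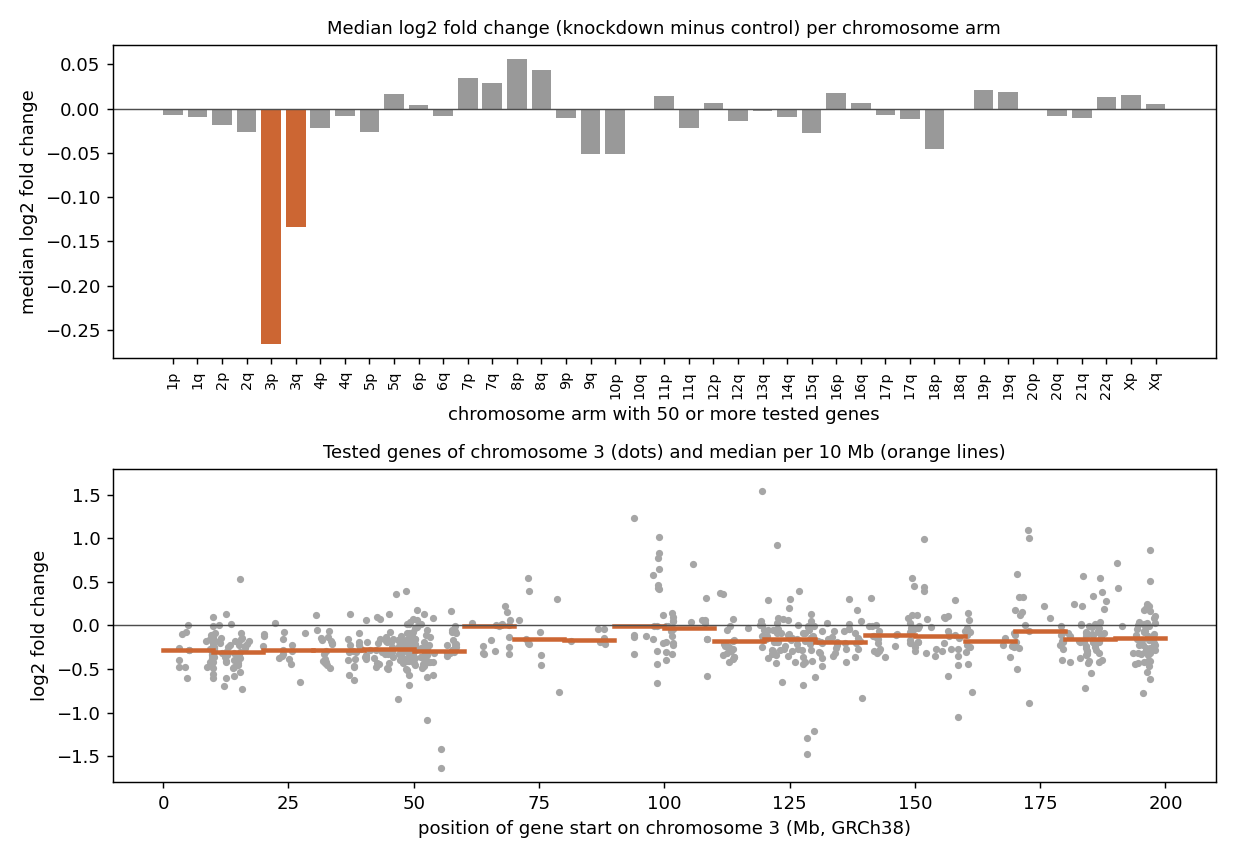
Top, median log2 fold change (knockdown minus control) of the tested genes of each chromosome arm, with 3p (-0.27) and 3q (-0.13) in orange. Bottom, log2 fold change of each tested gene of chromosome 3 by position in Mb on GRCh38 (grey dots) with the median of each 10 Mb (orange lines), which stays between -0.31 and -0.27 over the first 60 Mb.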

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

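The tests of scaling, of a 5 FPKM filter, of limma without the trend, of length and GC content and of leaving out chromosome 3 were chosen after the data were seen. SRSF10 stayed lower and past the threshold in all 16 alternatives, with log2 fold changes of -0.85 to -0.78, and -0.82 to -0.78 with a library left out. All called genes that an alternative tested kept their sign in it. For most alternatives this was fixed in advance and is no test. The groups of all 1542 higher and 1525 lower genes did not overlap, so leaving out a library could not reverse them. The filters, the pseudocount, the block and the fit without the trend could not do so either. With no filter, which tested 32280 genes, 1013 genes and 11 lists were lower. With a pseudocount of 0.1, 196 genes were 2-fold higher and 79 lower, and with a 5 FPKM filter, which tested 6824 genes, 39 and 15. Leaving out each library gave 894 to 1352 higher and 964 to 1327 lower genes, 58 to 113 and 25 to 45 of them by 2-fold or more, and 12 to 13 lists higher and 6 to 9 lower. Those fits have fewer libraries, and their filter still asked for 3. Genes that reach 1 FPKM in 1 group alone were therefore not tested when a library of that group was left out. Replicate numbers did not pair the samples: residuals of same-numbered libraries correlated at 0.016, 0.057 and -0.071, control 2 correlated best with knockdown 3 (0.088) and control 3 with knockdown 1 (0.129). The replicate block gave 1193 higher and 1146 lower genes. Of called genes 52.95% were higher with median-of-ratios scaling, 50.6% with quantile normalization and 49.5% without mitochondrially encoded genes, against 50.3%. With an estimated correlation camera called 0 lists higher and 0 lower. Over the 16 other alternatives 15 of the 20 called lists kept their call. The ribosomal protein, secreted liver, YAP/TAZ, histone and fetal liver lists did not, and the cause was not tested; 5 other lists gained a call in 1 to 4 alternatives. With the 5 FPKM filter the secreted liver list had too few members to test. Of 1983 values of 127 named genes, 1930 kept direction and side of the threshold, 53 kept direction only and none reversed. For the called genes among them the direction was likewise mostly fixed in advance. Count models, other count scalings and a minimum of 10 counts were not run, because the files hold FPKM. At these depths 1 FPKM is 12.72 to 14.35 fragments for a gene of 1 kb, so genes near the filter are the least certain.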

Other observations

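The tests on the short arm of chromosome 3, on runs of adjacent genes, on macrophage RNA, on liver transcripts and on the neighbours of MET were chosen after the results were seen, as were the gene families, the segments and the genes named here other than SRSF10, TFEC and GPNMB. The list of lysosomal and TFE-target genes was also drawn up after TFEC, GPNMB and lysosomal genes were seen to rise. Gene families, grouped by the stem of their symbols, were compared with all other tested genes. Of 125 families 7 passed at the preset correlation, and none with an estimated correlation (smallest adjusted p = 0.795). Some of their members, such as MCM2, SRSF2, IL1B and RPL14, are also in lists called above, so these family calls partly repeat those. Genes with the stem IL, mostly interleukins and their receptors, had 10 of 23 higher and 1 lower, and TNF receptor family genes (TNFRSF) 5 of 10 higher and 0 lower (camera adjusted p = 0.0278 for both). TNFRSF11B, the decoy receptor osteoprotegerin, rose from 0.523 ± 0.12 to 2.12 ± 0.091 FPKM, IL7R from 2.305 ± 0.79 to 7.27 ± 0.55 FPKM and IL32 from 2.6004 ± 0.26 to 5.13 ± 0.405 FPKM. TNFRSF11B, with a low control mean, passed the filter through the knockdown libraries, so its direction was largely set by the filter. Of genes with the stem POLR, mostly RNA polymerase subunits, 11 of 30 fell and 2 rose, and of PRPF genes 5 of 12 fell (camera adjusted p = 0.0278 for both). Of RPL genes 10 of 48 fell (camera adjusted p = 0.0278), 6 of them on chromosome 3, and without the genes of that chromosome the adjusted p was 0.139. Another of the 10, RPL22, lies in a stretch of chromosome 1 where 29 of 58 tested genes fell and 1 rose. Of 10 genes with the stem MCM 7 fell (camera adjusted p = 0.0254), while MCM8 (4.82 ± 0.18 and 4.996 ± 0.102 FPKM), MCM9 (1.303 ± 0.062 and 1.55 ± 0.11 FPKM) and MCM3AP, which encodes an MCM3-associated protein (9.36 ± 0.25 and 9.40 ± 0.12 FPKM), did not pass. Of 10 SRSF genes other than SRSF10, the gene knocked down, 6 fell (camera adjusted p = 0.0416, and 0.0254 with SRSF10), while SRSF5 (18.5 ± 0.072 and 16.99 ± 0.48 FPKM), SRSF11 (15.2 ± 0.24 and 13.9 ± 0.81 FPKM), SRSF9 (21.2 ± 0.058 and 21.8 ± 0.77 FPKM) and SRSF4 (10.96 ± 0.801 and 10.996 ± 0.69 FPKM) did not pass.

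Genes called as changed numbered 3067, and 3261 after a trend on gene length and GC content was removed. They numbered 3033 with median-of-ratios scaling and 3020 with quantile normalization, so neither that trend nor these scalings account for the number. The scalings moved the share of higher calls by at most 2.67 percentage points. With 10 splits of the 6 libraries no share under 0.05 can be reached; 1 of the 10, the real one, reached the real counts of 3067 genes, 131 genes changed 2-fold and 20 lists, and the highest of the others were 1, 1 and 14. The short arm of chromosome 3 had a median 0.266 below 0, and even the upper quartile of its genes with at least 5 FPKM was at -0.18. Fewer copies of much of that arm in the knockdown cultures would give such values. The shift did not span the whole arm evenly. Medians per 10 Mb were -0.31 to -0.27 over the first 60 Mb, but -0.0012 in the next 10 Mb (17 tested genes). The long arm had a median of -0.13. A copy number difference elsewhere stays open, since a run of 50 genes on chromosome 1 (5991466 to 12032045) had a median 0.252 below 0, while SRSF10 lies in the next stretch, with a median of 0.022. Chromosome 3 held 315 of the 1525 lower genes (185 on its short arm and 130 on its long arm) and shifted runs outside it 33 of 2718 calls. Gene dosage may account directly for part of these. On the other chromosomes 10.6% of tested genes were also called lower, so some of the 315 could be lower without it. Indirect effects of a differing subclone cannot be told apart from those of SRSF10, because all 3 knockdown libraries carry the shift.

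TFEC and GPNMB had the largest rises on the log2(FPKM + 1) scale, though not by the ratio of FPKM, and the autophagy and lysosome list was called higher (camera adjusted p = 3.41e-05; adjusted p = 0.136 with an estimated correlation). Macrophages express both, but the median of TYROBP, LYZ, CD68, AIF1, LAPTM5 and FCER1G in the knockdown libraries was 0.0276 FPKM, with TYROBP and AIF1 listed at 0, which argues against RNA of macrophages. A hypothesis is that targets of TFE-family factors were higher. Of 46 tested lysosomal and TFE-target genes in no earlier list, 19 rose and 1 fell, with a median log2 fold change of 0.12 (camera p = 1.098e-06, and 0.0752 with an estimated correlation). This list was drawn up after the rises above were seen and was tested on the same libraries, so it is not independent of them. It also holds general lysosomal genes, so it cannot single out targets of TFE-family factors. RRAGD rose from 10.2 ± 0.74 to 15.7 ± 0.36 FPKM and SCARB2 from 9.07 ± 0.201 to 12.04 ± 0.17 FPKM. Whether TFEC or another factor drives this was not tested.

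The libraries labelled Huh7 held little liver RNA and much MET. The median of AFP, ALB, APOA1, TTR, SERPINA1 and APOA2 was at most 0.363 FPKM in any library, which is consistent with another line than the label says. A Huh7 derivative that lost liver gene expression would give the same values (AFP at 0.8496 FPKM over all libraries), so these cannot be told apart here. MET was at 2286 ± 100.2 FPKM (SD over 6 libraries), rank 2 among nuclear genes. The 3 expressed protein-coding genes next to it on each side, 6 in all, had a median above that of 99.9% of 10095 such runs. Their values had been seen before the test. The 3 on one side had a median of 847 FPKM. Those on the other (CAPZA2 at 28.6, LSM8 at 3.28 and TSPAN12 at 1.84 FPKM) had 3.28, below the 7.53 FPKM of a typical run. A copy number gain therefore cannot be told apart from high expression of these genes. Genes around MET and TFEC, which lies beyond TES, moved in both directions. CAV1 (878 ± 67 to 1536 ± 101 FPKM) and CAV2 (782 ± 59 to 912 ± 24 FPKM) rose. So did TSPAN12 (1.15 ± 0.24 to 2.53 ± 0.29 FPKM). TES (228 ± 4.4 to 208 ± 2.2 FPKM) and ING3 (3.43 ± 0.13 to 2.65 ± 0.24 FPKM) fell. MET did not pass the test between groups (log2 fold change -0.08, limma adjusted p = 0.233). The nearest expressed protein-coding genes on either side of TFEC, MDFIC and TES, did not rise with it. MDFIC was at 143 ± 4.8 FPKM in the controls and 151 ± 4.4 FPKM in the knockdown (limma adjusted p = 0.172). These values argue against a copy number gain shared with MDFIC and TES as the source of the rise of TFEC. A gain of TFEC alone was not tested.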
